A study of Danio rerio with 4 samples.

How the data were processed

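RNA of whole embryos at 96 hours after fertilisation was compared on 4 zebrafish arrays with 2 colours each, TNNT2sp morphants in Cy3 and control morphants in Cy5. Per the labels' protocols, pools of 30 embryos were extracted with Trizol and columns, and 5 µg of total RNA was labelled with a low-input T7 kit. Per the file headers, the arrays were scanned and quantified with Agilent Feature Extraction 9.5.3.1, which gives for each spot the mean intensity and the local background intensity in both channels as deposited. The deposited series matrix holds log10 values whose scale and direction the labels do not state. Set against the scanner's own log10 ratio of Cy5 over Cy3, between 96.8% and 97.6% of its values per array equalled the negative of that ratio within 0.001, so they are log10 of Cy3 over Cy5, and nearly all of the rest (98.6% or more) had a scanner ratio of 0. The column medians were 0.000103, 0.00180, 0.00272 and 0.00131 on the log10 scale. All 4 arrays lay on 1 slide with 1 scan date, so no batch of that kind was there to test. The software's correlation between observed and nominal spike-in ratios was 0.974 to 0.982.

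Mean intensities were corrected with limma's normexp (offset 50) and normalised within each array by loess, with control spots at weight 0 and then removed. Spots flagged by the scanner as outliers or for uneven background were left out (329, 387, 597 and 651 per array), and spots of a probe were averaged. One step departed from the test as laid out. In replicate 3, 13 spots other than controls had a local background median above 500. With them in the normexp fit, the standard deviation of that array's log2 ratios was 0.0967, against 0.183 with no background correction and 0.200 to 0.244 on the other arrays. They were therefore left out before the fit, which gave 0.184. The limit of 500 and the step itself were chosen after the data and a first count of calls (2 genes) had been seen, and the count with the step was 550. A version leaving out every flagged spot before the fit, also chosen afterwards, gave a standard deviation of 0.114 and 95 calls.

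A probe was tested if well above background in at least 3 of 4 arrays in at least 1 channel, and with at least 3 values, which left 39119 of 43603 probes. The brightest tested probe stood for a gene, giving 31648 genes. Mean log2 ratios were tested against 0 with lmFit and eBayes (limma 3.58.1 in R 4.3.3, with data.table (1.17.8)), with Benjamini-Hochberg adjustment at 0.05. Probes were named through a reference gene list of the assembly GRCz12tu, used for names only: 16075 by accession, 2532 by gene identifier, 1046 by symbol and 1446 by synonym, and 22504 kept the file's name. Coordinates are those of the files, on danRer5 (Zv7), and no genome sequence was used here.

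Before the data were examined, the groups, the test, the alternatives, 26 gene lists and the rule for named genes were fixed. The rule named tnnt2a, the 12 highest and 12 lowest called genes with a real name and the same sign on 4 arrays, up to 4 members of each list with the smallest p, and a set of heart genes. nppb, one of that set, had no tested probe under that name. List members called by limma are named as well, and a few others, among them the liver carriers, globins and unnamed 2-fold transcripts, were chosen after their values were seen. The form of a clone name was widened after the names had been viewed. Lists were tested with camera (preset correlation 0.01) over genes with values on all arrays, adjusted over the 26 lists, with an estimated correlation and fry as alternatives.

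The other alternatives fixed beforehand were no background correction, the scanner software's processed signals, median centring, quantile normalisation between arrays, no filter and a strict filter on dim probes, an intensity trend with a robust prior, the series matrix, 8 channels as separate samples, the mean of all probes or each probe alone, and each replicate left out. Turning the sign of arrays was planned only for correlations below -0.3; those between arrays were 0.14 to 0.36, so it was not run. On simulated data for the 31648 genes, limma called 97 of 100 genes changed by 0.5 and 98 of 100 changed by 1 on the log2 scale, and 14 of 31448 unchanged ones. A simulated liver list shifted by 0.2 was called, with 0 of 25 other lists.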

Results

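Gene expression was measured in whole zebrafish embryos in which the splicing of tnnt2, the gene of cardiac troponin T, had been disturbed by a morpholino, an antisense oligonucleotide that blocks the processing of one transcript. The morpholino, called TNNT2sp in the labels, causes missplicing of exon 13. Embryos were injected at the 1- to 4-cell stage with it or with a control morpholino, kept at 28 degrees Celsius, and collected at 96 hours after fertilisation in pools of 30. On each of 4 two-colour arrays, RNA of a TNNT2sp pool in Cy3 was hybridised against RNA of a control pool in Cy5, and the labels describe the 4 pairs as biological replicates. Between 87.2% and 89.7% of probes were well above background in Cy3 and between 88.6% and 92.3% in Cy5, and 0 spots were saturated. The number of arrays, 4, limits the precision. All values are mean log2 ratios of TNNT2sp over control with their standard error (SE) from limma, and gene symbols follow the current reference table where it held the probe's accession.

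The comparison of TNNT2sp with control embryos asks first what became of the targeted transcript. The probe of tnnt2a (A_15_P192466) at chromosome 23, positions 39030339 to 39030841 of the Zv7 assembly, fell by 2.27 on the log2 scale (SE 0.10, n = 4), a 4.83-fold lower signal, with a limma adjusted p of 0.00523 among all probes. This call was lost in both other versions of a background step described below (0.0781 and 0.0595), and kept in the alternatives fixed beforehand that were tried on it. This probe spans 503 bases of the genome, against 60 bases for the other tnnt2a probe (A_15_P211696) at positions 39039048 to 39039107. The latter had a log2 ratio of -0.99 (SE 0.15, n = 3, lower on 3 of 3 arrays), and as the brighter of the pair it stood for the gene in the gene-level fit, where its limma adjusted p was 0.0470. Among all probes, the fit used for the first probe, it was 0.0533 and did not pass. Where each probe lies relative to exon 13 was not determined, so the pair measures tnnt2a signal at these places and not the share of misspliced transcript. The second probe's gene-level call was kept in 6 alternatives and lost in 7, among them no background correction (limma adjusted p 0.0572), and without replicate 1, 3 or 4 it had too few values to be tested.

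Among heart genes, nppa, which encodes the natriuretic peptide of the atrium, rose by 1.42 (SE 0.10, n = 3, limma adjusted p 0.0175), a 2.67-fold increase, at a probe on chromosome 8, positions 44603961 to 44604020. Its remaining probes gave 1.19 (SE 0.09, n = 4) and 1.17 (SE 0.09, n = 4), higher on 4 of 4 arrays each. The transcription factor gene mef2ca fell by 0.45 (SE 0.06, n = 4, limma adjusted p 0.0305). Other probes of mef2ca gave -0.39, -0.20 and -0.11, none past the threshold, the last of them higher on 2 of 4 arrays. The myosin heavy chain gene myh6 had a log2 ratio of 0.60 (SE 0.14, n = 4) and did not pass (limma adjusted p 0.0941). The ventricular heavy chain vmhc, listed under its current symbol myh7, stood at 0.13 (SE 0.13, n = 4), and the light chain myl7 at 0.07 (SE 0.08, n = 4), neither past the threshold. Of 23 sarcomere genes of the heart, 0 rose and tnnt2a alone fell (1 and 2 adjusted over the list alone). Of 15 genes of cardiac calcium handling and conduction none passed over all genes, with casq2 at 0.34 (SE 0.07, n = 4) the 1 that did adjusted over the list alone. Of 24 genes of natriuretic signalling and hypertrophic growth, nppa rose and mef2ca fell (1 and 3 adjusted over the list alone). None of these 3 heart lists shifted as a whole (camera adjusted p 0.692, 0.690 and 0.506), and for the last the median (0.03) and mean (0.02) were positive while camera, which leaves out genes lacking a value on an array, nppa among them, gave a negative direction. Fast (27 genes) and slow (16 genes) skeletal muscle lists held 0 called genes, also adjusted over the list alone, and did not pass (camera adjusted p 0.975 and 0.752), though the fast list passed downward without replicate 3 (0.0196).

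**Figure D1:**
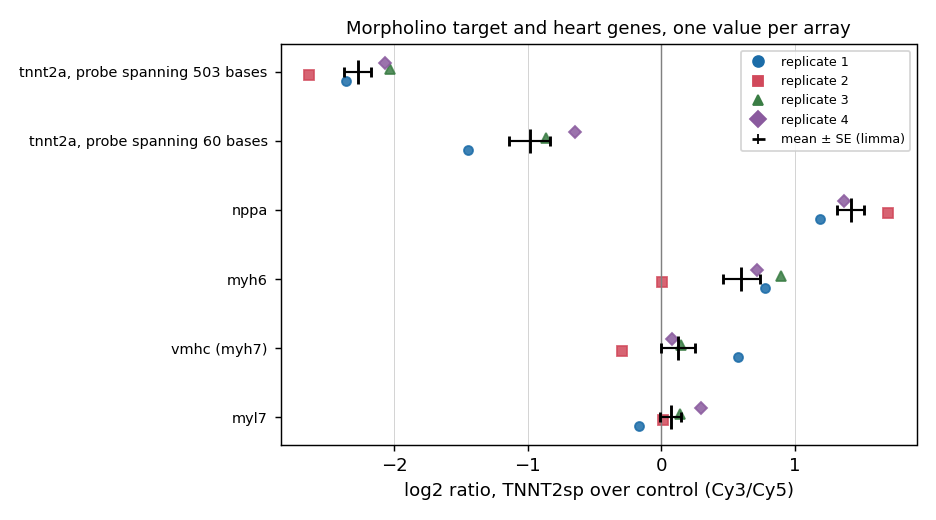
Log2 ratio of TNNT2sp over control (horizontal axis) for both tnnt2a probes and for nppa, myh6, vmhc and myl7, with a coloured symbol per array and a black mark with bars for the limma mean and SE. The tnnt2a probe spanning 503 bases lies between -2.63 and -2.03 on 4 arrays, nppa between 1.19 and 1.70 on 3, and the myl7 values fall on both sides of 0.

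The second question was which transcripts differed across the whole embryo. Complement component c3a.2 rose by 1.08 (SE 0.07, n = 4, limma adjusted p 0.00867), the complement gene c9 by 0.75 (SE 0.05, n = 4, limma adjusted p 0.00849), and the fatty acid desaturase fads2 by 0.91 (SE 0.05, n = 4, limma adjusted p 0.00574). Among the transcripts that fell was plekhf1, by 1.08 (SE 0.09, n = 4). Of 31648 genes tested with limma, 203 were higher and 347 lower in TNNT2sp at a Benjamini-Hochberg adjusted p below 0.05. All 550 had the same sign on every array that measured them, which largely follows from calling them on these same few values. At an unadjusted p below 0.05 there were 2684 higher and 3078 lower genes, where chance alone would give 1582 in all. The total rests on a step chosen after a first count had been seen: 13 spots of replicate 3 with very bright local background were left out before the background model was fitted. With those spots kept, as the test had first been laid out, limma called 2 genes, c3a.2 and c9, both higher. Leaving out every spot the scanner software had marked, with no limit on the background, gave 95 calls, and no background correction at all, an alternative fixed beforehand, gave 501, of which 489 were among the 550. With median centring in place of loess, 91 genes were higher and 275 lower. Among other alternatives fixed beforehand, the scanner software's processed signals gave 136 calls and the series matrix 132. The 8 channels as separate samples gave 11, and quantile normalisation between arrays 580.

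A 2-fold change was passed by 9 of the higher and 4 of the lower genes. With the test as first laid out these were 1 and 0, and with the scanner software's processed signals or the series matrix 15 and 36, so which direction held more depends on the processing. The named ones were nppa, c3a.2, serpinf2a and shbg among the higher and plekhf1 among the lower. The other lower ones, given here after their values were seen, were the unnamed transcripts LOC559763 at -1.45 (SE 0.18, n = 4), LOC100006438 at -1.19 (SE 0.07, n = 4) and BQ078317 at -1.09 (SE 0.08, n = 4).

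Among called named genes with values of the same sign on 4 arrays, the 12 with the highest ratios included c3a.2. The plasma serpin gene serpinf2a rose by 1.04 (SE 0.12, n = 4), shbg, which encodes a carrier of sex steroids, by 1.02 (SE 0.13, n = 4), the pentraxin gene apcs by 0.94 (SE 0.14, n = 4) and complement factor cfb by 0.83 (SE 0.12, n = 4). The others were dhrs13a.2 (0.91), fads2 (0.91), apoda.1 (0.87), itln3 (0.85), lgals3bp.3 (0.83), env (0.81) and cbln14 (0.81). The largest limma adjusted p of these 12 was 0.0347, for apcs. Second probes of fads2 and shbg passed as well, at 0.84 and 0.98. That of apcs, at 0.88, did not (limma adjusted p 0.0510).

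By the same rule, which leaves out genes with 3 values such as tnnt2a and grk1b, the 12 with the lowest ratios were plekhf1, plekhs1.3 (-0.98), the sulfate transporter slc13a1 (-0.78), ghrh (-0.72), ino80db (-0.67), pde8a (-0.65), apoea (-0.59), bmerb1 (-0.58), mob1a (-0.56), pomca (-0.56), pdlim5a (-0.55) and il20ra (-0.55). Of these, pomca encodes the precursor of pituitary corticotropin, and ghrh encodes a releasing hormone of growth hormone. The ghrh signal was well above background on only 2 of 4 arrays in TNNT2sp, against 4 of 4 in control. Its ratio and rank are therefore imprecise. The log2 intensity in control was 17.5 for ino80db, 17.3 for pde8a, 16.8 for mob1a, and 15.9 for bmerb1 and apoea. The median over both channels was 8.45 for all genes tested, 10.72 for called lower and 10.64 for called higher genes. Others of these 12 were dimmer, such as plekhs1.3 (9.55) and slc13a1 (9.28). Whether signal near the top of the range shaped these ratios was not tested. For pde8a, pdlim5a and il20ra other probes of the same gene lay near 0, at -0.01 for pde8a, -0.09 for pdlim5a, and -0.02 and -0.12 for il20ra. That of plekhs1.3 was at -0.93, lower on 4 of 4 arrays (limma adjusted p 0.0621). Over all called genes with a second tested probe, that probe had the same sign for 66 of 69 higher genes (median 0.25 against 0.40 for the first probe) and for 49 of 71 lower genes (median -0.06 against -0.40), 95.7% and 69.0%, against 72.2% of all genes with a higher and 57.0% of all genes with a lower first probe. A name was carried by 126 of the 203 higher genes and 144 of the 347 lower ones, 62.1% and 41.5%, against 40.4% of all genes tested.

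**Figure D2:**
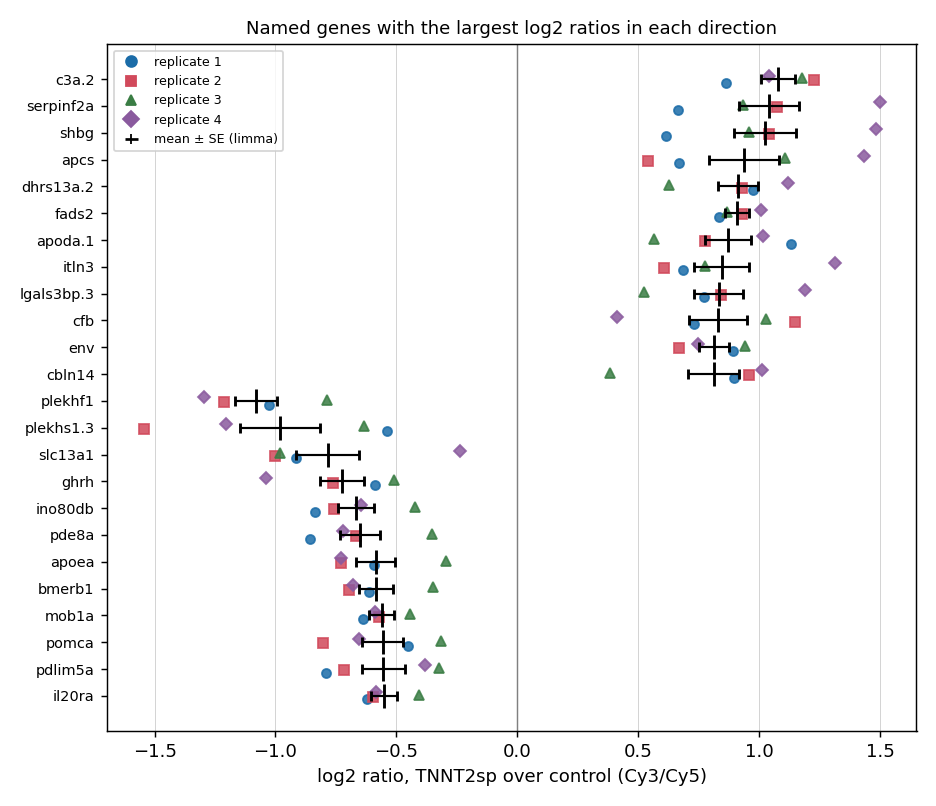
Log2 ratio of TNNT2sp over control (horizontal axis) of the 12 highest and 12 lowest called named genes with values on 4 arrays, with a coloured symbol per array and a black mark with bars for the limma mean and SE. All symbols of a gene lie on one side of 0, from 1.498 for serpinf2a to -1.54 for plekhs1.3, each on a single array.

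Leukocyte markers rose as a group by camera (adjusted p 2.39e-10; adjusted p = 0.103 with an estimated correlation). Of 41 tested, 7 rose and 0 fell over all genes (16 rose and 1 fell adjusted over the list alone), and 36 were above 0. The 7 were the plastin gene lcp1 at 0.59 (SE 0.07, n = 4), the macrophage gene mpeg1.1 at 0.53 (SE 0.07, n = 4), coro1a at 0.47, spi1b, a transcription factor of myeloid cells, at 0.47, mfap4.1 at 0.47, c1qc at 0.43 and cebpa at 0.33. The list median was between 0.13 and 0.20 on each array. For this list fry, which asks only whether the genes move one way on balance, gave an adjusted p of 0.0243. Markers of endothelium (33 genes) did not pass (camera adjusted p 0.0733, and 0.0481 without replicate 4), with dll4 higher by 0.33 (SE 0.06, n = 4) and hey2, also a Notch pathway gene, lower by a log2 ratio of -0.31 (SE 0.05, n = 4), both called, also adjusted over the list alone.

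Liver genes rose as a group by camera (adjusted p 6.24e-07; adjusted p = 0.463 with an estimated correlation), with 7 of 47 called higher and 1 lower (18 and 2 adjusted over the list alone). The clotting genes f2 (0.59, SE 0.05, n = 4), f5 (0.59, SE 0.08, n = 4), fgb (0.36, SE 0.05, n = 4) and f9b (0.36, SE 0.05, n = 4) rose, as did c9, vtna and hpda, while apoea fell. Of 25 carriers and enzymes of the liver, 19 were above 0 and hpda was the called one. Among the others were fabp10a at 0.70 (SE 0.29, n = 4), tfa at 0.67 (SE 0.16, n = 3), rbp4 at -0.33 (SE 0.07, n = 4) and apoa1b at -0.36 (SE 0.16, n = 4), none past the threshold. The median of the liver list was 0.08, 0.17, 0.21 and 0.33 in replicates 1 to 4, the same order of arrays as for the exocrine pancreas list below. Acute inflammatory genes, which share c9 with the liver list, rose by camera (adjusted p 0.0135; adjusted p = 0.463 with an estimated correlation). Of 28 tested, c3a.2, apcs, cfb, c9 and nfkbiab, an inhibitor of NF-kB, rose and timp2b fell (6 and 1 adjusted over the list alone). Of the 28, 17 were above 0, with hamp at -0.95 (SE 0.35, n = 4) and lect2l at -0.32 (SE 0.12, n = 4), neither past the threshold. The list median was -0.04 in replicate 4 against 0.04 to 0.27 in the others. This list's call was also lost without replicate 2 (camera adjusted p 0.188) and without replicate 3 (0.0680).

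Red blood cell genes were mixed. Of 35 tested, 5 rose and 2 fell (12 and 3 adjusted over the list alone). The first enzyme of haem synthesis, alas2, rose by 0.78 (SE 0.08, n = 4), followed by epb41b of the membrane skeleton (0.62), hemgn (0.59), the erythroid transcription factor klf1 (0.38) and tspo (0.35). The 2 that fell were creg1, by 0.53 (SE 0.06, n = 4), and rhd, by 0.49 (SE 0.06, n = 4). Globin genes did not pass, ranging from -0.25 for hbae3 (SE 0.08, n = 3) to 0.71 for hbae5 (SE 0.40, n = 4). The camera adjusted p of the list was 0.00883 (adjusted p = 0.463 with an estimated correlation; 0.0680 with camera's preset correlation without replicate 3).

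Photoreceptor genes fell as a group by camera (adjusted p 2.07e-05; adjusted p = 0.536 with an estimated correlation). Of 49 tested, 43 were below 0, but only the kinase gene grk1b fell by itself, by 0.55 (SE 0.08, n = 3), with 5 lower adjusted over the list alone. The cone arrestin gene arr3a stood at -0.49 (SE 0.09, n = 4) and the rod gene saga at -0.33 (SE 0.07, n = 4), neither past the threshold, and the list median was 0.08 in replicate 4 against -0.18 to -0.44 in the others. The shift of the list, -0.15, was -0.07 without replicate 3 (camera adjusted p 0.0273) and -0.26 without replicate 4. Nervous system genes also fell by camera (adjusted p 0.0010; adjusted p = 0.463 with an estimated correlation), with 43 of 55 below 0 and 2 lower adjusted over the list alone. The GABA synthesis gene gad1b was the called one at -0.45 (SE 0.07, n = 4), and its other probes lay between -0.16 and 0.09. The respiratory chain list fell by camera (adjusted p 0.0137; adjusted p = 0.558 with an estimated correlation) with 0 of 51 genes called by limma, 0 over the list alone, and this was lost without replicate 1 (0.334) and without replicate 2 (0.248). With median centring the shift of the respiratory chain list, -0.06, was -0.15 (1.67e-09), and that of nervous system genes, -0.09, was -0.14.

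Lists of DNA replication and mitosis (55 genes, camera adjusted p 6.83e-05), fatty acid oxidation (40 genes, 0.000298) and extracellular matrix (41 genes, 0.0251) rose by small amounts, with medians of 0.08, 0.10 and 0.09 and 0 genes called over all genes (adjusted p = 0.536, 0.463 and 0.463 with an estimated correlation). Adjusted over the list alone, limma called 3 higher and 1 lower gene of replication and mitosis, 2 higher of fatty acid oxidation, and 5 higher and 3 lower of the matrix. Examples were mcm7 at 0.36 (SE 0.07, n = 4), acadl at 0.30 (SE 0.06, n = 4) and col6a1 at 0.23 (SE 0.05, n = 4), none past the threshold over all genes. Another probe of col6a1 stood at -0.09, higher on 1 of 4 arrays. The median of the replication list was 0.16 in replicate 1, and without that array the camera adjusted p was 0.0555; the matrix list was lost without replicate 1 (0.127) and without replicate 2 (0.103), and the shift of fatty acid oxidation, 0.08, was 0.05 without replicate 4 (0.0259).

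The remaining lists did not pass with all 4 arrays. Targets of p53, which off-target effects of morpholinos can raise, had a camera adjusted p of 0.975 over 28 genes, with gadd45ab higher by 0.52 (SE 0.07, n = 4, limma adjusted p 0.0247) and 4 genes higher adjusted over the list alone. The first probe of gadd45ba, at 0.25 (SE 0.05, n = 4), did not pass, while its other probes did, at 0.45 and 0.44 (limma adjusted p 0.0299 and 0.0255 among all probes). The p53 list had a median of -0.04 and a mean of -0.01, and fry gave the positive direction. For the unfolded protein response (27 genes, 0.205, and 0.0400 without replicate 4) xbp1 rose by 0.31 (SE 0.05, n = 4) and sdf2l1 fell by 0.45 (SE 0.06, n = 4), with 2 genes in each direction adjusted over the list alone. Interferon response (27 genes, 0.692), hypoxia response (43 genes, 0.222) and heat shock (33 genes, 0.0948, and 0.00773 with median centring) held 0 called genes over all genes, and adjusted over the list alone 5 heat shock genes were lower. The glucocorticoid and circadian list (29 genes, 0.0766, and 0.0485 without replicate 3) held pomca as its called gene, and glycolysis (33 genes, 0.425) gapdhs, at -0.46 (SE 0.06, n = 3), whose other probes stood at -0.08 and 0.03. Adjusted over the list alone, 1 gene was lower in the former and 1 higher and 1 lower in the latter. The gut, pancreas and eye lens lists varied between arrays more than they shifted. The exocrine pancreas list (29 genes, 0.690) had medians of -0.74, -0.08, 0.18 and 0.89 in replicates 1 to 4, lens crystallins (36 genes, 0.249) -0.31, 0.32, -0.63 and 0.10, and the intestine list (39 genes, 0.478) -0.22, 0.13, -0.06 and 0.45. Their calls followed single arrays: pancreas passed upward without replicate 1 (9.91e-05) and downward without replicate 4 (0.00401), lens downward without replicate 2 (0.000161) and without replicate 4 (0.0439), and intestine upward without replicate 1 (0.00433). The intestinal hormone gene fgf19 rose by 0.81 (SE 0.12, n = 4, limma adjusted p 0.0312), the 1 gene of these 3 lists called, also adjusted over the list alone.

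**Figure D3:**
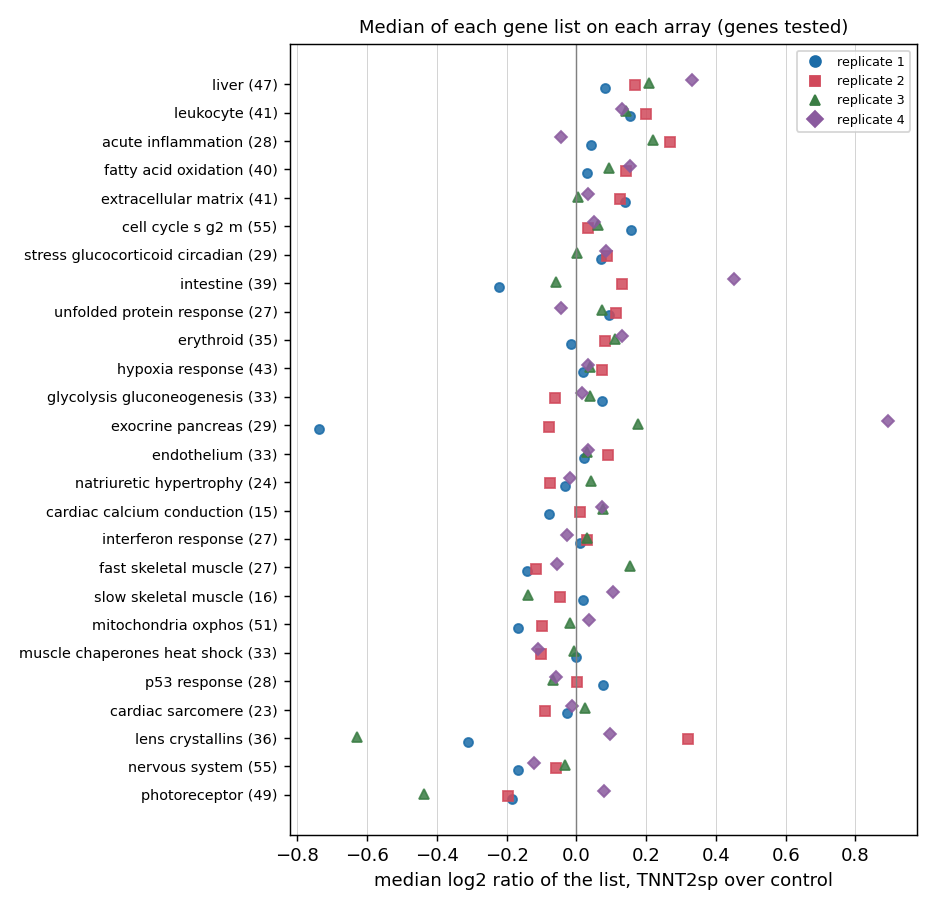
Median log2 ratio of TNNT2sp over control of each of the 26 gene lists (horizontal axis), with a coloured symbol per array and the number of genes tested in brackets. The leukocyte and liver medians lie above 0 on all 4 arrays, as do those of lists that did not pass, such as endothelium and hypoxia response. The exocrine pancreas medians run from -0.74 to 0.89.

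Each array had TNNT2sp in Cy3 and control in Cy5, so a dye effect specific to a probe or gene cannot be separated from the effect of the morpholino in any of these values. Leaving out 1 array in turn lowered the calls to 44 without replicate 1, 1 (LOC568005) without replicate 2, 11 without replicate 3 and 27 without replicate 4. The higher genes were 72.7%, 100%, 54.5% and 44.4% of these calls in turn, against 36.9% of the 550. Which direction held more calls therefore depends on the arrays used.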

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

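Of the tests in this part, only the comparison of complement and coagulation genes of the liver with its carriers and enzymes was chosen before its result was seen, though values of some complement genes were known by then. All others were chosen after all or part of their results had been seen.

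Among 144 sets of 4 array values, 5 held an array far from the other 3, where chance gives about 7.2. Replicate 4 stood apart for slc13a1 (-0.24, the others -1.003 to -0.916), for hmgcs1 (0.67, the others 0.22 to 0.29) and for saga (-0.11, the others -0.43 to -0.38). Replicate 1 stood apart for lpla (0.46, the others 0.16 to 0.21), and replicate 2 for the median of the endothelium list (0.0915, the others 0.0221 to 0.0327).

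The first pattern is that second probes matched the lower genes less well than the higher ones. Of second probes of lower genes 69.0% were lower too (49 of 71, 95% exact interval 56.9% to 79.5%), against 57.0% among all genes with a lower first probe, which lies within the interval, so a dye effect of single probes is not excluded. The reference was changed more than once after this result had been seen, and the first one, an even split, lies below the interval. Being called added less to the agreement among genes with a lower first probe than among those with a higher one (logistic model, interaction p = 0.0115), a test that replaced Fisher's exact test of 69.0% against 95.7% (p = 3.66e-05), which ignored the different base rates. Of these second probes 3 of 71 passed by themselves, against 14 of 69 of the higher genes. Signal of single probes, from a dye effect or cross-hybridisation, may therefore account for part of the lower calls, and a response to the morpholino stays open. Names were carried by 41.5% of the lower genes, near the 40.4% of all genes tested. Among the higher genes the share was 62.1% (Fisher's exact test of higher against lower, p = 3.99e-06). All genes tested are not a like reference for either. Their median log2 intensity was 8.45, against 10.72 for the lower and 10.64 for the higher genes.

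The second pattern is the rise of complement and coagulation genes of the liver. Of 13 such genes tested, 13 were above 0 and 6 were called higher. The group was not one of the 26 lists and had no camera test of its own. The liver list lost its call with an estimated correlation (camera adjusted p 0.463). A larger share of liver RNA as the whole cause is argued against for these genes. The median of 13 complement and coagulation genes exceeded that of 25 liver carriers and enzymes by 0.26 (SE 0.04, higher on 4 of 4). The median of the carriers and enzymes was itself at 0.13 (SD 0.15), with 19 of the 25 above 0. The SE of the difference is over arrays and does not cover the spread among genes. The carriers and enzymes, at -0.04, 0.17, 0.07 and 0.32 in replicates 1 to 4, ran in the order of the intestine list, so part of their change may be a share of gut organs that differed between pools. This was not tested. Second probes were higher for 8 of 8 genes (100%, 95% exact interval from 63.1%). Even this highest possible count leaves the 72.2% among all genes with a higher first probe within the interval. With 8 genes the test could therefore not have excluded a dye effect of single probes. The median of these second probes was 0.40, against 0.37 for the first probes of the same genes. For second probes of all genes with a higher first probe it was 0.06. The rise was thus not confined to the first probes. A dye effect shared by all probes of a gene was not tested. A response of these genes to the morpholino and a dye effect both stay open.

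The third pattern is the rise of leukocyte markers. A lower share of the main tissues would raise other minor cell types alike. The leukocyte median exceeded the endothelial one by 0.11 (SE 0.01, higher on 4 of 4 arrays). Above 0 were 36 of 41 leukocyte and 21 of 33 endothelial genes. This goes against an equal rise of leukocyte and endothelial markers. The SE is over arrays and does not cover the spread among genes. Endothelium was the only other minor cell type compared, with dll4 called higher and hey2 lower. Whether minor cell types rose alike in general is therefore not settled. Second probes were higher for 92.3% (12 of 13, 95% exact interval from 64.0%), and as the same 72.2% lies within this interval, a dye effect of single probes stays open. More leukocytes and more transcript per cell stay open too, and neither was tested here.

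For the count of 550 genes, the 8 ways of assigning the 2 channels of each array to the groups are too few for a share under 0.05. The real assignment gave 550, the highest of the others 0, and so 1 of the 8 gave as many.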

How the results depend on the processing

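The number of calls depends on the background step in replicate 3, where leaving out the bright-background spots or every scanner-flagged spot was chosen after seeing the data. With the bright-background spots kept, as first laid out, 2 genes were higher and 0 lower (1 and 0 at 2-fold), tnnt2a stood at -0.88 and the endothelium list passed (shift 0.0457). With every scanner-flagged spot left out before the fit, 30 were higher and 65 lower (4 and 1 at 2-fold), tnnt2a at -0.94. All 550 genes kept their sign in both. This says little, since each had 1 sign on every array that measured it and mainly replicate 3 changed. Processed signals of the scanner software gave 47 higher and 89 lower (15 and 36 at 2-fold), the series matrix 47 and 85 (15 and 36), and median centring 91 higher genes, a share of 24.9% of its calls against 36.9%. tnnt2a kept its sign but lost its call at -0.99 without background correction, -1.05 with processed signals and -1.05 with the series matrix. The tnnt2a probe spanning 503 bases kept its call in all alternatives tried on it except with the bright-background spots kept (-2.03, limma adjusted p 0.0781) and with every flagged spot left out before the fit (-2.15, 0.0595).

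With the pairing within arrays ignored (no replicate block, 8 channels as separate samples), 3 genes were higher and 8 lower (2 and 2 at 2-fold), and tnnt2a (-0.99) and the inflammation (0.15) and matrix (0.0435) lists lost their calls. The channels of an array share its spots, so the paired ratio was the main test. Leaving out 1 array in turn gave 1 to 32 higher, 0 to 15 lower, 1 to 8 at 2-fold higher and 0 to 6 at 2-fold lower, the lowest without replicate 2, with fewer arrays in each fit. tnnt2a ranged from -2.35 to -0.99, since without replicate 1, 3 or 4 the brighter probe has too few values and the other stands for the gene.

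List shifts over the same leave-one-out fits ranged from 0.0918 to 0.22 for inflammation, 0.0374 to 0.0859 for the cell cycle, 0.0432 to 0.0582 for endothelium, 0.0948 to 0.17 for red blood cells, 0.0221 to 0.0537 for matrix, -0.26 (without replicate 4) to -0.0718 (without replicate 3) for photoreceptors, 0.0472 (without replicate 4) to 0.11 for fatty acid oxidation, -0.11 to 0.0150 for fast muscle, -0.0601 to 0.17 for intestine, -0.23 to 0.0387 for lens, -0.0887 to -0.0248 for the respiratory chain, 0.0356 to 0.0782 for glucocorticoid genes and 0.0147 to 0.0559 for the unfolded protein response. Exocrine pancreas ranged from -0.24 to 0.28, past the threshold downward without replicate 4 (-0.24) and upward without replicate 1 (0.28). Calls were also gained for lens without replicate 2 (-0.23) and 4 (-0.16), intestine without replicate 1 (0.17), fast muscle and glucocorticoid genes without replicate 3 (-0.11 and 0.0782), and endothelium and the unfolded protein response without replicate 4 (0.0582 and 0.0559). With median centring the heat shock list passed (-0.10), and cell cycle (0.0379), matrix (0.00235) and fatty acid oxidation (0.0481) did not, while the called respiratory chain (-0.15) and nervous system (-0.14) lists moved further from 0. The matrix list was at 0.0665 with processed signals and 0.0666 with the series matrix. The respiratory chain lost its call with processed signals (-0.0436), the series matrix (-0.0444) and background-flagged spots kept (-0.0456). Keeping the background-flagged spots was not among the alternatives fixed beforehand, and it gave 633 called genes. With an estimated correlation all 10 called lists lost their calls, at unchanged shifts: cell cycle 0.0738, inflammation 0.15, matrix 0.0435, respiratory chain -0.0637, fatty acid oxidation 0.0839, red blood cells 0.13, leukocytes 0.20, photoreceptors -0.15, liver 0.20 and nervous system -0.0899. The estimated correlation itself was -0.00475 for leukocytes and 0.0102 for matrix, below or near the preset 0.01. A higher correlation therefore does not explain the loss for leukocytes and matrix. The estimated correlation was 0.245 for liver and 0.333 for photoreceptors. With an estimated correlation camera also uses far fewer degrees of freedom, those left by the 4 arrays, so a pass over 26 lists is harder to reach. For leukocytes the unadjusted camera p went from 9.19e-12 to 0.00398. How much of each loss comes from this was not tested. fry kept the call of leukocytes only. Other causes of these changes were not tested. The remaining count and list results kept their side of the threshold, though 19 list shifts that passed in neither setting changed sign. Over all alternatives, named genes kept their side in 1570 comparisons, lost a call in 370 and gained one in 5, and 6 of the values that passed in neither setting changed sign.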

Other observations

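The tests in this part were all chosen after some of the genes had been seen, and genes already named or seen were left out of the tested lists, which had first been run with the prompting genes included. The 5 unnamed transcripts at least 2-fold higher include LOC568005, with the highest ratio of all called genes (2.05, SE 0.10, n = 4), at chromosome 8, positions 44610363 to 44610422 of Zv7, on the same stretch as the nppa probe at 44603961. The unnamed si:ch211-103n10.5 (1.501, SE 0.19, n = 4) lies at chromosome 8, positions 28304221 to 28304280, near the probe of the macrophage gene mpeg1.1 at 28295363. Hepcidin, hamp, was at -0.95 (SE 0.35, n = 4), lower on 4 of 4 arrays, without passing.

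One hypothesis, prompted by fads2 and dhcr7 (0.55, SE 0.07, n = 4), is that sterol and unsaturated fat synthesis rose as a pathway. Of 25 further genes, 23 were above 0 with a median of 0.23, among them hmgcra (0.38, SE 0.10, n = 4) and lss (0.36, SE 0.07, n = 4), and 0 were called by limma. The 2 below 0 were the desaturase genes scd (-0.05) and scdb (-0.05). The elongase genes elovl6, elovl5 and elovl2 stood at 0.03, 0.11 and 0.27. Camera gave an adjusted p of 8.31e-08 over the 3 lists, 0.113 with an estimated correlation and 0.0383 by fry. A joint rise of the list may be present, but its call was lost in 1 of these tests. Beyond fads2, a rise of the unsaturated fat part is not shown, and that part was not tested by itself.

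A second hypothesis, from cd74b (0.66, SE 0.07, n = 4), ifi30b (0.69, SE 0.07, n = 4), ctsba (0.60, SE 0.05, n = 4) and ctsl.1 (0.74, SE 0.11, n = 4), is that antigen presentation and lysosomal genes rose together. Of 28 further genes 23 were above 0, with a median of 0.14, and psap was called at 0.31 (SE 0.05, n = 4). Among the further genes, mhc2a, cd74a and ifi30a of antigen presentation stood at 0.05, -0.02 and 0.11. The cathepsin genes ctss1 and ctss2.1 stood at 0.32 and 0.44, and none of these was called. Camera gave an adjusted p of 1.29e-05, 0.113 with an estimated correlation and 0.0383 by fry. A joint rise of the list may be present here with the same limit. Antigen presentation genes were not tested apart from lysosomal ones.

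A further hypothesis, from pomca and ghrh, is that pituitary hormones and their releasers fell together. Of 21 further genes 16 were below 0, with a median of -0.14. Growth hormone gh1 was called at -0.37 (SE 0.04, n = 4), while prl stood at -0.43 (SE 0.11, n = 4) without passing. The list was wider than this theme, and the 16 include other neuropeptide genes, such as npy (-0.23), hcrt (-0.21) and cart2 (-0.17). Hormone genes above 0 included fshb (0.11) and pomcb (0.08). Camera gave an adjusted p of 0.00199, 0.205 with an estimated correlation and 0.0580 by fry. A joint fall of this mixed list may be present, but its call was lost in 2 of these tests. Pituitary hormones by themselves were not tested. pomca and ghrh had 1 tested probe each, and ghrh was well above background in TNNT2sp on only 2 of 4 arrays.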
